A study of Mus musculus with 9 samples.

How the data were processed

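The series measured miRNAs with 9 one-colour Agilent mouse miRNA arrays. The RNA came from osteoblastic cells that were grown out of the marrow of male C57BL/6 mice aged 8 weeks. Marrow cells were cultured for 7 days and then kept for 7 days in a medium that drives osteoblast differentiation, per the labels' protocols. Alpha particles were then given at doses of 0, 0.5 and 1 Gy, at 0.22 Gy per minute, with 3 arrays per dose. Sample titles gave the dose and the replicate number. No label says that the 3 samples of a dose came from separate animals or cultures, so the p-values measure the spread between these samples, which may be technical. The time between irradiation and RNA extraction is not given in the sources used here.

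Each deposited scanner file holds the spot intensity values of 1 array, made with Agilent Feature Extraction 11.5.1.1, per the file headers. The processed intensity had been detrended and background-subtracted by that software and was not normalized between arrays, per the file headers. The other deposited columns used here were the median spot and background intensity, the total gene signal, and 0 or 1 marks for spots above background, outliers and saturation. An array has 58594 spots, of which 56430 carry probes for 1881 mouse miRNAs (4415 probes) and 2164 are controls. The names of the miRNAs are those of the array design. A table of the whole series was not used here, because its 9 columns of values carry names that match no sample title. The header of the scanner files names an older mouse genome build than the gene table given, so no coordinates are printed.

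Spots that the scanner software marked as non-uniform or as population outliers were left out, and no spot was saturated. A probe's value was the mean processed intensity of its spots. A probe counted as detected on an array when at least 50% of its remaining spots were well above background, and a miRNA when 1 or more of its probes was. Each array was scaled on the 75th percentile over the 45 probes detected on all 9 arrays. The value of a miRNA was the sum of its scaled probes, raised to a floor of 11.5 scaled units where it was lower (the 1st percentile of detected values), and then taken to log2. The log2 floor was 3.52, and values at the floor have no order. Tests covered the 134 miRNAs detected on all arrays of at least 1 dose. Of these, 40 were detected on all arrays of 0.5 Gy or of 1 Gy, and the others passed through 0 Gy alone. The tested set therefore favours miRNAs that were detected at 0 Gy. Array 1 of 0.5 Gy and of 1 Gy had a high background, so failing the filter at those doses need not mean a lower level. The number passing was 175 without array 1 of 0.5 Gy, 171 without array 1 of 1 Gy and 166 without array 2 of 1 Gy. It was at most 147 without any other array. Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3 over all 9 arrays, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The comparisons were 0.5 against 0 Gy, 1 against 0 Gy, 1 against 0.5 Gy, any difference among the 3 doses (moderated F test) and a linear slope on dose. Figures were drawn with matplotlib.

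miRNA lists were tested with camera of limma at a preset correlation of 0.01, then with an estimated correlation and with fry, and adjusted over the lists of a comparison. Lists with fewer than 3 tested members received values and no test. The lists covered p53-responsive miRNAs, miRNAs that target DNA repair genes, the miR-15/16 family, the miR-17 cluster that holds miR-92a-3p and its paralogs, the let-7 family, osteoblast-promoting and osteoblast-inhibiting miRNAs, NF-kB and inflammation, the Dlk1-Dio3 cluster, the Sfmbt2 cluster and muscle. Marker lists covered myeloid, erythroid and platelet, lymphoid, endothelial, mesenchymal, epithelial, liver and neuronal cells. The text names every miRNA past the threshold in a comparison and then those with the smallest unadjusted p up to 10, 2 to 4 members of each list, the 10 most abundant miRNAs, and miRNAs detected on all arrays of 1 dose and on none of another. List members are named for the comparisons with 0 Gy; for 1 against 0.5 Gy the lists are given by their means. The groups, the lists, the tests, this rule and the alternatives listed next were set before the data were examined.

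The alternatives set in advance changed the scaling, the background correction, the summary of probes, the detection filter and call, the floor, the blocks for slide and replicate number, the variance model, the arrays in the fit, and left out each array in turn. Normexp had been planned on the mean spot intensity and was run on the median spot intensity, because the scanner files used here hold no mean column. Added after the data were seen were fits without array 1 of every dose, without the 2 irradiated arrays of number 1, with array weights, and of the 0.5 and 1 Gy arrays with the replicate number as a block. The default fit of the array weights stopped before it converged, so a gene by gene fit of the weights was run as well, and both are reported. The pairing comes from the data and not from the labels. The deviations from the dose means of same-numbered arrays correlated at 0.84, 0.75 and 0.59 between 0.5 and 1 Gy, all over 0.1, so for that comparison the numbers were taken to pair the samples. Pair 1 holds the 2 irradiated arrays of number 1, which had a high background. Pair 2 holds the only arrays of slide 3. The correlations thus cannot tell paired samples from a shared background or slide. The paired fit was run on the miRNAs that its own 6 arrays pass (40) and, after that result was seen, on the 134. After a first run of the alternatives, the fit with an intensity trend was also passed to camera, which had ignored it.

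The tests were tried on simulated data with the means and spreads of these 134 miRNAs, with 28 of them changed between 1 and 0 Gy in each of 100 simulations. The share recovered was 8.14% at a fold of 2, 53.3% at 4, 84.1% at 8 and 97.1% at 16. Each simulation gave on average 0.78 false calls, and the unchanged comparison of 0.5 with 0 Gy gave 0.01. The simulated noise was drawn independently for each miRNA and array, with the same spread on every array and no floor. The real arrays share structure, with 58.6% of the variance on 1 principal component. The simulated figures therefore hold only for independent noise. The median spread of a miRNA within a dose was 0.81 on the log2 scale. The number of arrays limits the precision.

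The arrays lay on 3 slides scanned on 2 days. Slide 1 held arrays 1 and 3 of every dose, slide 2 held array 2 of 0 Gy, and slide 3 held array 2 of 0.5 Gy and of 1 Gy. Closely related miRNAs, such as members of the let-7 family, can bind each other's probes, so values of single members are uncertain. Probe sequences were not used here.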

Results

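The arrays gave a miRNA profile of marrow-derived osteoblastic cells at 3 doses of alpha particles, with 3 arrays per dose. Of the 1881 miRNAs on the array, 446 were detected on at least 1 array, 28 on all 9 and 1435 on none. The number detected per array was 234, 157 and 185 at 0 Gy, 216, 173 and 195 at 0.5 Gy, and 144, 223 and 178 at 1 Gy, for arrays 1, 2 and 3. The additive error of the scanner software was 19.4 on array 1 of 0.5 Gy and 11.2 on array 1 of 1 Gy, and between 1.60 and 2.83 on the other 7 arrays.

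The miRNAs of highest mean log2 signal over the 9 arrays were miR-494-3p (11.49), miR-1224-5p (11.32), miR-3473b (10.88), miR-5126 (10.71), miR-8110 (10.62), miR-8117 (10.32), miR-3960 (10.31), miR-6366 (10.22), miR-709 (10.07) and miR-7005-5p (10.01). Probes of different miRNAs differ in their response, so this order is one of signal and not of amount. Without array 1 of 0 Gy, miR-494-3p stood at 10.93, below miR-1224-5p (11.09) and miR-3473b (10.97). On array 1 of 0 Gy, miR-494-3p took 53.9% of the summed miRNA signal. Its share on the other 8 arrays lay between 2.65% and 6.95%. Of the 10 miRNAs of the stromal list 5 were detected on any array and 2 were tested, miR-125b-5p at a mean of 8.41 and miR-214-3p at 7.54. miR-181a-5p of the lymphoid list was detected on all 9 arrays at a mean of 7.25. Of the 7 myeloid markers 2 were detected, miR-223-3p on 5 of 9 arrays and miR-342-3p on 4. These values do not set the share of each cell type. No miRNA of the erythroid and platelet, endothelial, muscle, epithelial, liver or neuronal lists was detected on any array.

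The first comparison asked which miRNAs differed between cells given 0.5 Gy and unirradiated cells. The let-7 family, known for restraining proliferation genes such as Ras and Lin28, had 10 members on the array, of which 8 were detected on any array and 3 passed the detection filter. These 3 had higher means at 0.5 Gy. let-7a-5p differed by 1.65 (SE 1.17), let-7b-5p by 1.40 (SE 0.84) and let-7c-5p by 1.60 (SE 1.01) on the log2 scale. The stromal miRNAs miR-125b-5p and miR-214-3p, both listed as inhibitors of osteoblast differentiation, stood at 8.94 ± 0.43 and 7.78 ± 1.09 at 0.5 Gy, and at 7.38 ± 1.89 and 6.87 ± 1.72 at 0 Gy (mean log2 ± SD, n = 3). After quantile normalization the difference of miR-214-3p turned to -0.22. let-7a-5p, let-7b-5p and let-7c-5p differed by 0.35, 0.60 and 0.55 without array 1 of 0 Gy, miR-125b-5p by 0.62 and miR-214-3p by 0.046. Without array 3 of 0 Gy they differed by 2.94, 2.45, 2.81, 2.51 and 1.77. None of these miRNAs passed the test, and 0 of 134 miRNAs did so with limma at an adjusted p of 0.05; 2 had an unadjusted p under 0.05, where chance gives 6.7. Leaving out each array in turn, that number ran from 0 (without array 1 of 0 Gy or of 0.5 Gy) to 14 of 143 miRNAs (without array 3 of 0 Gy).

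The smallest unadjusted p values belonged to miR-125a-5p, a miRNA of the NF-kB list, and miR-92a-3p, which comes from the oncogenic miR-17 cluster. miR-125a-5p was higher at 0.5 Gy by 2.02 (SE 0.76, unadjusted p = 0.0250, limma adjusted p = 0.561) and miR-92a-3p by 1.95 (SE 0.86, unadjusted p = 0.0483, limma adjusted p = 0.561). Without the high-background array 1 of 0.5 Gy the values were 1.55 and 1.08, and without array 1 of 0 Gy miR-125a-5p stood at 1.32. On that array of 0.5 Gy the miRNAs read 8.01 and 8.04 against at most 6.72 and 5.52 on the other 0.5 Gy arrays. Each was the only tested member of its list, so that adjusted over the list alone 1 of 1 member passed in both lists. The other miRNAs of smallest p, none of which passed, were miR-193b-3p (1.60), miR-370-3p (-1.85), miR-188-5p (-1.75), miR-331-3p (1.33), miR-6385 (-2.24), miR-135a-1-3p (-1.99), miR-125b-5p (1.56) and miR-6238 (-1.66). Without array 1 of 0.5 Gy, miR-193b-3p stood at 0.92, miR-331-3p at 0.64, miR-370-3p at -1.21 and miR-188-5p at -0.88. miR-370-3p, miR-188-5p, miR-6385, miR-135a-1-3p and miR-6238 read 8.53, 9.79, 10.05, 9.32 and 8.36 on array 1 of 0 Gy, and at most 6.00, 7.42, 5.83, 5.71 and 5.00 on the other 8 arrays. Without array 1 of 0 Gy they differed by -0.91, -0.92, -0.80, -0.74 and -0.53, and miR-125b-5p by 0.62. The median difference of all tested miRNAs was -0.47, and relative to it miR-125a-5p stood 2.49 and miR-370-3p -1.39. Over the same 134 miRNAs that median was -0.12 without array 1 of 0.5 Gy and -0.28 without array 1 of 0 Gy. With the filter applied again, leaving out array 1 of 0.5 Gy gave 0.011 over 175 miRNAs, and the values relative to it were 1.54 and -1.22. miR-328-5p was detected on all 0 Gy arrays and on no 0.5 Gy array, and its level lay too near the detection limit for a fold.

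As a list, let-7 had a mean difference of 1.55 and lay above the other miRNAs in camera of limma (adjusted p = 0.00164), with 0 of 3 members past the test over all miRNAs and 0 of 3 adjusted over the list alone. This call was lost with an estimated correlation (adjusted p = 0.177) and in fry (adjusted p = 0.460). In camera let-7 is set against the other tested miRNAs, most of which passed the filter through 0 Gy alone. Of the 134, 96 were lower at 0.5 Gy. Among miRNAs detected on all 9 arrays the median difference was 0.0087, and let-7 did not pass (camera adjusted p = 0.0811). The let-7 mean difference was 0.32 when scaled on all probes (camera adjusted p = 0.0238), 0.585 after quantile normalization (0.00107), 1.12 without scaling (0.000135) and 1.21 after normexp (0.448). The first 3 of these calls were lost with an estimated correlation (adjusted p = 0.368, 0.153 and 0.0989). Without a filter, all 8 detected members entered, with a mean difference of 1.00 (camera adjusted p = 0.862). The median was 0.92 over the 1011 miRNAs of that fit, which left out those at the floor on every array. The mean let-7 signal was 5.83, 7.67 and 10.30 on the 0 Gy arrays and 8.53, 9.71 and 10.22 on the 0.5 Gy arrays, with array 3 of 0 Gy above all irradiated arrays. The exact two-sided permutation p of the mean was 0.4, where 0.1 is the smallest that 3 against 3 arrays allow. With slide as a block the mean difference was 1.28 (adjusted p = 0.0165, and 0.190 with an estimated correlation), and within the slide that holds 6 arrays it was 1.31 (adjusted p = 0.154). Without array 1 of 0 Gy 5 members passed the filter, with a mean difference of 0.21 (camera adjusted p = 0.238), and the mean of the 3 members tested above was 0.50. Without array 3 of 0 Gy the mean of these 3 was 2.74, with a camera adjusted p of 2.44e-06 and 0.0583 with an estimated correlation.

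**Figure D1:**
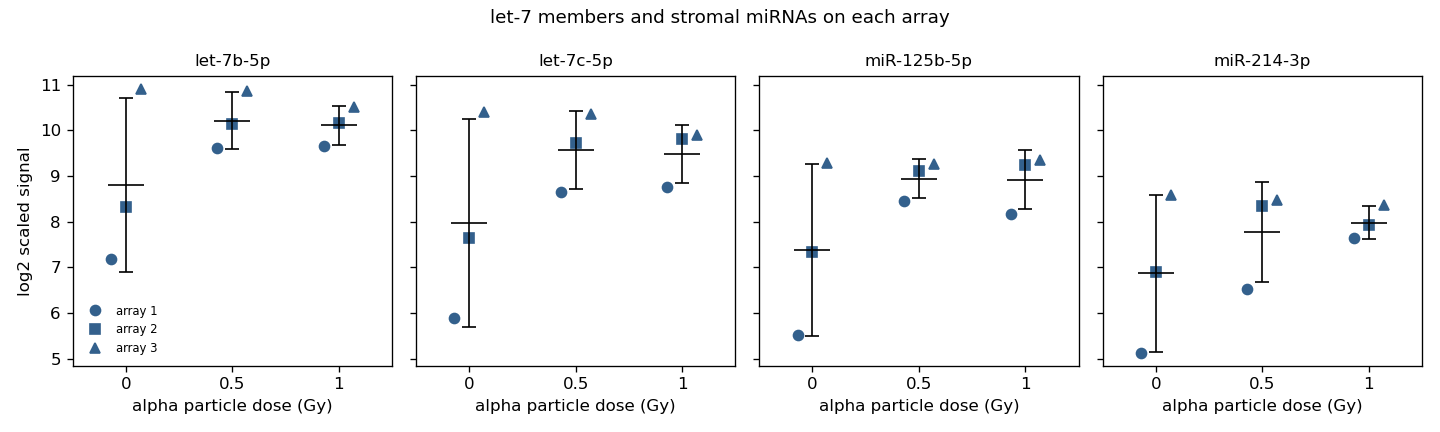
Log2 scaled signal of let-7b-5p, let-7c-5p, miR-125b-5p and miR-214-3p on each array against alpha particle dose in Gy; symbols are arrays 1 to 3, and the bars show the mean and SD of 3 arrays. At 0 Gy let-7b-5p ran from 7.19 to 10.90 and miR-125b-5p from 5.51 to 9.29; on the irradiated arrays their highest values were 10.87 and 9.34.

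The Sfmbt2 cluster is a large group of miRNAs in an intron of the Sfmbt2 gene. Its list was filled by the start of the miRNA names, and the genomic place of its members was not checked. The list had 5 tested members, of which 2 were higher and 3 lower at 0.5 Gy. All but miR-466i-5p of these 5 passed the filter through 0 Gy alone, and 96 of all 134 tested miRNAs were lower. The mean difference of the cluster was -0.13 and its median -0.20, while camera placed it above the other miRNAs without passing (adjusted p = 0.549), because the other miRNAs had a lower median still. miR-466i-5p differed by -0.45 and miR-669p-3p by -0.57. After normexp the mean of the list turned to 0.38 and miR-669p-3p to 0.51. The mean also turned to 0.069 with slide as a block, 0.055 within the slide that holds 6 arrays, 0.018 without array 2 of 0 Gy, 0.072 without array 1 of 0.5 Gy and 0.15 over 13 members without a filter. With each array left out, miR-669p-3p ran from -1.14 (without array 3 of 0.5 Gy) to 0.23 (without array 1 of 0.5 Gy), and miR-466i-5p from -0.70 to -0.15 (without arrays 3 and 1 of 0 Gy). In the Dlk1-Dio3 cluster, an imprinted miRNA group, miR-494-3p differed by -1.45 (SE 1.23) and miR-370-3p by -1.85 (SE 0.90). The value of miR-494-3p turned to 0.34 without array 1 of 0 Gy and to 0.26 after quantile normalization, and was -2.46 without array 3 of 0 Gy. The osteoblast-promoting miR-3960 and miR-2861, which act on Hoxa2 and Hdac5 upstream of Runx2, differed by -0.38 and -0.36. miR-2861 turned to 0.23 after normexp, and miR-3960 to 0.055 with slide as a block and 0.11 within the slide that holds 6 arrays. Leaving out each array in turn, miR-3960 ran from -0.54 to -0.053 and miR-2861 from -0.62 to -0.085. The lymphoid miR-181a-5p differed by 0.86 (SE 0.49), with the direction turned when scaled on all probes (-0.40) and after quantile normalization (-0.45), and ran from 0.55 to 1.33 with each array left out.

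The second comparison set 1 Gy against 0 Gy. miR-3473b, miR-3963 and miR-6366 were the miRNAs with the smallest p, and each had its 3 arrays at 1 Gy above its 3 arrays at 0 Gy. Of 134 miRNAs 13 had these 6 arrays apart in this way, in either direction, where chance gives 13.4. The 3 miRNAs varied together over the 9 arrays (r = 0.953, 0.791 and 0.765), so they are not 3 independent findings. miR-3473b stood at 11.93 ± 1.19 at 1 Gy against 9.95 ± 0.39 at 0 Gy, miR-3963 at 10.93 ± 1.19 against 8.93 ± 0.50, and miR-6366 at 10.97 ± 0.42 against 9.38 ± 0.78 (mean log2 ± SD, n = 3). Their differences were 1.98 (SE 0.65), 2.00 (SE 0.67) and 1.59 (SE 0.54), each with a limma adjusted p of 0.539. With limma 0 of 134 miRNAs passed, and 4 had an unadjusted p under 0.05, where chance gives 6.7. Leaving out each array in turn, that number ran from 2 (without array 1 of 0 Gy or array 3 of 1 Gy) to 18 of 143 miRNAs (without array 3 of 0 Gy).

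The other miRNAs of smallest p, none of which passed, were miR-370-3p (-2.14), miR-125a-3p (-1.005), miR-125a-5p (1.66), miR-3620-5p (-1.15), miR-7226-5p (-1.32), miR-6385 (-2.34) and miR-3960 (-0.89). With array 1 of 0 Gy left out, miR-370-3p stood at -1.20, miR-6385 at -0.90 and miR-125a-5p at 0.96. Without array 3 of 0 Gy miR-125a-5p stood at 2.496, without array 1 of 1 Gy miR-7226-5p at -0.83, and without array 2 of 0 Gy miR-3960 at -0.56. After normexp miR-125a-3p turned to 0.15 and miR-3620-5p to 0.013. The median difference of all tested miRNAs was -0.49, and relative to it miR-3473b stood 2.47, miR-3963 2.49 and miR-6366 2.08. Over the same 134 miRNAs it was -0.33 without array 1 of 1 Gy and -0.78 without array 2 of 1 Gy. With the filter applied again, leaving out array 1 of 1 Gy gave -0.026 over 171 miRNAs, and the 3 values relative to it were 2.65, 2.62 and 1.85. With slide as a block the median difference of these 3 miRNAs was 1.34, and within the slide that holds 6 arrays it was 1.22.

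**Figure D2:**
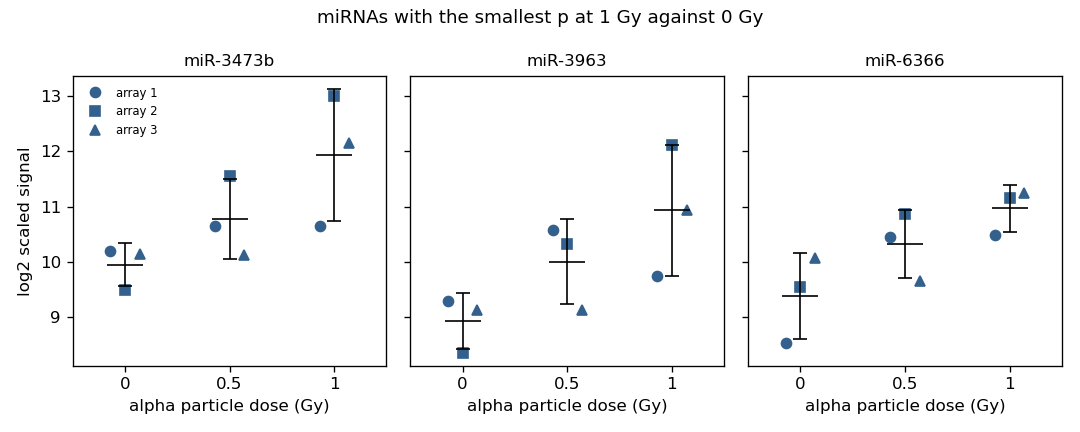
Log2 scaled signal of miR-3473b, miR-3963 and miR-6366 on each array against alpha particle dose in Gy; symbols are arrays 1 to 3, and the bars show the mean and SD of 3 arrays. miR-3473b lay between 9.50 and 10.20 at 0 Gy and between 10.64 and 13.00 at 1 Gy.

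The 3 let-7 members had a mean difference of 1.496 at 1 Gy, from 1.31 for let-7b-5p to 1.67 for let-7a-5p. This mean was 0.25 when scaled on all probes (camera adjusted p = 0.00556), 0.96 after quantile normalization (0.00137), 1.23 without scaling (0.000778) and 1.08 after normexp (0.0978). The first 3 of these calls were lost with an estimated correlation (adjusted p = 0.246, 0.162 and 0.146). With each array left out, let-7a-5p ran from 0.37 to 2.96, let-7b-5p from 0.50 to 2.36 and let-7c-5p from 0.46 to 2.72, lowest without array 1 and highest without array 3 of 0 Gy. camera of limma gave an adjusted p of 0.00375, with 0 of 3 members past the test over all miRNAs or adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.217) and in fry (adjusted p = 0.247), and the exact two-sided permutation p of the mean was 0.4. At 1 Gy 100 of the 134 tested miRNAs were lower, and most had passed the filter through 0 Gy alone. Among miRNAs detected on all 9 arrays the median difference was 0.14, and let-7 did not pass (camera adjusted p = 0.154). Without a filter the 8 detected members had a mean difference of 0.99 (camera adjusted p = 0.117). With slide as a block the mean difference was 1.22 (adjusted p = 0.0157, and 0.376 with an estimated correlation), and within the slide that holds 6 arrays it was 1.19 (adjusted p = 0.144). Without array 1 of 0 Gy 5 members passed the filter, with a mean of 0.21 (camera adjusted p = 0.213), and the mean of the 3 members tested above was 0.44. Without array 2 of 1 Gy these 3 gave 1.32 (adjusted p = 0.0941). Without array 3 of 0 Gy they gave 2.68, with a camera adjusted p of 3.90e-06 and 0.0627 with an estimated correlation. Both comparisons use the same 0 Gy arrays, so their let-7 values are not independent.

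The stromal and osteoblast-inhibiting miR-125b-5p and miR-214-3p differed by 1.54 (SE 0.84) and 1.11 (SE 0.85) at 1 Gy, with miR-214-3p turning to -0.13 when scaled on all probes. They differed by 0.61 and 0.24 without array 1 of 0 Gy, and without array 3 of 0 Gy by 2.496 and 1.96. miR-92a-3p differed by 1.44 and miR-181a-5p by 0.83, the latter turning to -0.41 when scaled on all probes. With each array left out, miR-92a-3p ran from 0.87 to 2.01 and miR-181a-5p from 0.52 to 1.30. The osteoblast-promoting miR-3960 and miR-2861 differed by -0.89 (SE 0.46) and -0.40 (SE 0.44), and ran from -1.13 to -0.56 and from -0.66 to -0.25 with each array left out. In the Sfmbt2 cluster all 5 tested members were lower, with a mean of -0.44 (camera adjusted p = 0.535), miR-669p-3p at -0.76 and miR-466q at -0.73. Of all 134 tested miRNAs 100 were lower, and all but miR-466i-5p of these 5 had passed the filter through 0 Gy alone. The count of 5 thus says little about the cluster. After normexp the mean of the cluster turned to 0.10, miR-669p-3p to 0.18 and miR-466q to 0.19. miR-494-3p differed by -1.31 (SE 1.23), by 0.48 without array 1 of 0 Gy, by -2.32 without array 3 of 0 Gy and by 0.023 after quantile normalization.

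The third comparison set 1 Gy against 0.5 Gy. The 10 miRNAs of smallest p were miR-5099 (-0.95), miR-3473b (1.16), miR-3473a (1.32), miR-3963 (0.92), miR-5113 (-0.66), miR-7005-5p (1.03), miR-690 (1.00), miR-6378 (0.81), miR-6978-5p (-0.65) and miR-6366 (0.64), and none passed over all 9 arrays. miR-5099 lay at the floor on every 1 Gy array and on array 3 of 0.5 Gy, so its difference is set by the floor and is not exact. With limma 0 of 134 miRNAs did so, 0 had an unadjusted p under 0.05, and the smallest adjusted p was 0.999. With each array left out, 0 to 4 had an unadjusted p under 0.05 (4 of 171 without array 1 of 1 Gy). Without array 2 of 1 Gy, miR-3473b, miR-3473a, miR-3963, miR-690, miR-7005-5p and miR-6378 were at their lowest, 0.62, 0.48, 0.33, 0.34, 0.61 and 0.47. The first 4 were highest without array 1 of 1 Gy, at 1.80, 2.24, 1.52 and 1.89. miR-5113 and miR-6978-5p stood at -0.28 and -0.27 without array 2 of 0.5 Gy, and at -1.05 and -1.12 without array 1 of 0.5 Gy. Against the floor values of 1 Gy, miR-5099 stood at -0.52 without array 1 and -1.42 without array 3 of 0.5 Gy. miR-6366 stood at 0.31 without array 3 of 0.5 Gy. In a paired fit of the 0.5 and 1 Gy arrays, chosen after the data were seen, 3 of the 40 miRNAs detected on all arrays of either dose passed. They were miR-3473a (limma adjusted p = 0.00957), miR-3473b (0.0237) and miR-7005-5p (0.0471), each higher at 1 Gy. The same paired fit over the 134 miRNAs passed 0, with 10 at an unadjusted p under 0.05 and a smallest adjusted p of 0.103. With 2 residual degrees of freedom limma gave every miRNA of a paired fit 1 shared variance (SE 0.34 for the 40), so the spread of each miRNA did not count. The differences of pairs 1, 2 and 3 were 0.59, 1.55 and 1.83 for miR-3473a, 0.00030, 1.45 and 2.02 for miR-3473b, and 0.14, 1.60 and 1.36 for miR-7005-5p. Pair 1 holds the arrays of high background and pair 2 the only arrays of slide 3, so the pairing cannot be told apart from background and slide. The let-7 list differed by -0.06 on average (camera adjusted p = 0.887) and the Sfmbt2 list by -0.32 (camera adjusted p = 0.0688, and adjusted p = 0.163 with an estimated correlation). With each array left out, the mean of the 3 let-7 members ran from -0.54 (without array 1 of 0.5 Gy) to 0.31 (without array 3 of 0.5 Gy or array 1 of 1 Gy). The Sfmbt2 list passed without array 2 of 0.5 Gy (adjusted p = 0.0421) or array 3 of 1 Gy (0.0491), and did not with an estimated correlation (0.164 and 0.154). Its mean was -0.082 without array 3 of 0.5 Gy (adjusted p = 0.576) and -0.52 without array 1 of 0.5 Gy (0.737), and turned to 0.13 with a floor of 1 scaled unit (0.619). The mean differences were 0.09 for the stromal list, -0.27 for the osteoblast-promoting list and -0.08 for the Dlk1-Dio3 list, each with 2 tested members. These means depend on single arrays. On arrays 1, 2 and 3 the stromal mean was 7.49, 8.73 and 8.87 at 0.5 Gy and 7.90, 8.59 and 8.85 at 1 Gy. The osteoblast-promoting mean was 8.24, 8.34 and 8.57 against 8.40, 8.06 and 7.87, and the Dlk1-Dio3 mean 7.43, 8.04 and 8.17 against 7.24, 8.09 and 8.09.

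Over the 3 doses together, miR-3473b, miR-3963 and miR-6366 had linear slopes of 1.98, 2.00 and 1.59 log2 units per Gy, each with a limma adjusted p of 0.448. The slope passed for 0 of 134 miRNAs, with 5 at an unadjusted p under 0.05. The moderated F test passed for 0 of 134, with 3 at an unadjusted p under 0.05 and a smallest adjusted p of 0.752. With each array left out, the slope gave 3 to 13 unadjusted p values under 0.05 (13 of 175 without array 1 of 0.5 Gy) and the F test 0 to 9 (9 of 143 without array 3 of 0 Gy).

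Lists tied to the radiation response and to bone were mostly below the detection filter. The p53-responsive list had 3 of 13 members detected on any array, namely miR-34a-5p on 6 arrays, miR-107-3p on 5 and miR-22-3p on 5, and 0 were tested. Among miRNAs that target DNA repair genes, miR-24-3p was detected on 6 arrays and miR-103-3p on 5, and 0 of 15 were tested. When array 1 of 0.5 Gy was left out, 3 members each of the p53-responsive and DNA repair lists passed the filter, with miR-107-3p on both. Camera then called both lists higher at 0.5 Gy (adjusted p = 0.0369 and 0.0375) and neither at 1 Gy. These were 2 of 6 lists called higher at 0.5 Gy in that fit, so the rise was not particular to them. The camera adjusted p was smaller for the let-7 (0.000140), osteoblast-inhibiting (0.000516), stromal (0.00543) and NF-kB (0.0234) lists. All 6 calls were lost with an estimated correlation (adjusted p = 0.356 for the p53-responsive and DNA repair lists and 0.326 for the others). The miR-15/16 family had miR-15b-5p on 6 arrays and miR-16-5p and miR-497a-5p on 4, and 0 of 6 tested. Among osteoblast-promoting miRNAs, miR-29a-3p was detected on 6 arrays and miR-26a-5p on 5. All fixed lists together, with those of cell types and genomic clusters, held 216 miRNAs of the array, of which 50 were detected on any array and 17 were tested.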

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

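No test in this part was chosen after its result was seen. Of 20 kinds of control probe, each compared with 0 Gy at both doses, 1 negative-control probe at 1 Gy had all 3 arrays above all 3 arrays of 0 Gy, where chance gives 2 among the 40 comparisons. The lowest of its 1 Gy values was 1.03 times the highest 0 Gy value.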

How the results depend on the processing

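The fits without array 1 of every dose, without the 2 irradiated arrays of number 1, with array weights and of the paired 0.5 and 1 Gy arrays were added after seeing the data; the others were planned. The counts of miRNAs past the threshold were 0 under all 28 alternatives of both comparisons with 0 Gy and all 27 of the F test and the slope. At 1 against 0.5 Gy they were 0 under 29 of 30, and 3 in the paired fit of 40 miRNAs. Over them the smallest adjusted p of limma was 0.190 at 0.5 against 0 Gy, 0.0774 at 1 against 0 Gy, 0.00957 at 1 against 0.5 Gy, 0.243 in the F test and 0.0586 for the slope. Array weights gave 31 unadjusted p values under 0.05 at 1 against 0 Gy and 34 for the slope when fitted gene by gene, and 19 and 20 by default. The planned deposited table was not run (columns without sample titles). The median difference at 1 against 0 Gy moved to -1.08 when scaled on all probes, -0.95 after quantile normalization, -0.72 without scaling, 0.11 after normexp and, with other miRNAs passing the filter, -0.026 without array 1 of 1 Gy and 0.075 without array 1 of every dose.

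The list count at 0.5 against 0 Gy, 1 as reported, was 0 after normexp, with miRNAs detected on all 9 arrays, without a filter, on the slide with 6 arrays and with an estimated correlation. It was 5 without array 1 of every dose and 6 without the 2 irradiated arrays of number 1 (0 in both with an estimated correlation, smallest adjusted p 0.480 and 0.363), and lay between 0 and 6 when each array was left out. At 1 against 0 Gy the list count, 1 as reported, was 0 after normexp, with miRNAs detected on all 9 arrays, on the slide with 6 arrays and with an estimated correlation. It was 2 without the 2 irradiated arrays, and between 0 and 3 when each array was left out. Each of these calls was lost with an estimated correlation (adjusted p = 0.473 without the 2 arrays, and from 0.0627 to 0.635 with each array left out). The list count was also 1 without a filter and without array 1 of every dose, for a lower Sfmbt2 list (adjusted p = 0.00277 and 0.00814, with an estimated correlation 0.392 and 0.764) and not let-7 (0.117 in both). At 1 against 0.5 Gy, 0 as reported, it was 1 when scaled on all probes, with the mean of the probes' log2 values, with the scanner's detection call, without array 1 of every dose and without the 2 irradiated arrays, and between 0 and 1 when each array was left out. The list was Sfmbt2, lost each time with an estimated correlation (adjusted p from 0.154 to 0.960).

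Of 1415 recomputed values of named miRNAs, 22 reversed and 3 passed the threshold, miR-3473b (1.16), miR-3473a (1.32) and miR-7005-5p (1.03) in the paired fit of 40 miRNAs, and no cause of reversals was tested. At 0.5 against 0 Gy, normexp gave 0.23 for miR-2861 and 0.51 for miR-669p-3p. The slide as a block gave 0.055 and the slide with 6 arrays 0.11 for miR-3960. Quantile normalization gave -0.22 for miR-214-3p, 0.26 for miR-494-3p and -0.45 for miR-181a-5p, and all probes -0.40 for miR-181a-5p. miR-494-3p was 0.16 without array 1 of every dose and ran from -2.46 to 0.34 (without array 1 of 0 Gy) when each array was left out. miR-669p-3p was 0.23 without the 2 irradiated arrays and ran from -1.14 to 0.23 (without array 1 of 0.5 Gy) when each array was left out. At 1 against 0 Gy, normexp gave 0.15 for miR-125a-3p, 0.013 for miR-3620-5p, 0.19 for miR-466q and 0.18 for miR-669p-3p. All probes gave -0.13 for miR-214-3p and -0.41 for miR-181a-5p. miR-494-3p was 0.023 after quantile normalization, 0.56 without array 1 of every dose, between -2.32 and 0.48 (without array 1 of 0 Gy) when each array was left out and 0.031 with the default array weights.

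With the replicate number as a block, 0 miRNAs passed in all comparisons and 1, 1 and 0 lists, as without it. Deviations of same-numbered arrays correlated between -0.13 and 0.16 where 1 of them was a 0 Gy array, and these were not taken as pairs, though 7 of 9 arrays correlated best with an array of their own number. The paired fits of the 0.5 and 1 Gy arrays changed no call but those of the 3 miRNAs above and gave 0 lists.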

Other observations

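The tests of a shared slide, labelling, lower RNA input, irradiation, background and scaling below, and the splits of the paired arrays, were chosen after the results were seen; the other splits of the arrays and the test of 1 RNA on a pair of arrays were set before their own results.

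Principal components of the 134 tested miRNAs did not order the arrays by dose. The first, with 58.6% of the variance, placed array 1 of 0.5 Gy (15.57) and array 1 of 1 Gy (11.38) at one end and array 1 of 0 Gy (-12.33) at the other. Over the 3875 probes detected on none of the other 7 arrays, the same pair of irradiated arrays correlated with r = 0.997 across probes, which are not independent replicates. The highest r of either of them with another array over these probes was 0.915. On 1 or both of those 2 arrays (66 on both) and on none of the other 7, 145 miRNAs were detected.

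Array 3 of 0 Gy and array 3 of 0.5 Gy were nearly alike, with r = 0.996 across 134 miRNAs and an SD of their log2 differences of 0.18 over 182 miRNAs detected on both. Among the other 14 pairs of arrays on that slide the highest r was 0.964, which argues against the slide alone. The SD was 2.82 times what spot error gives, between the cutoffs set in advance, under 2 for 1 RNA on both arrays and 4 or more against it. Spot error holds no variation of labelling or hybridization between arrays, and no technical replicate sets the scale of these cutoffs. The ratio therefore cannot decide. In the other pairs of arrays it ran from 8.83 to 69.1. The next pair had an SD of 0.47. A shared RNA source therefore stays open. The pairs of 0 Gy arrays correlated at 0.707 to 0.918, with SDs of 0.94 to 1.64. These values argue against a lack of response at 0.5 Gy as the only cause of the likeness. A lack of response in 2 samples of 1 culture stays open.

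The let-7 members were low on arrays 1 and 2 of 0 Gy, at 5.83 and 7.67 against 10.30 on array 3, which lay above all irradiated arrays. The labelling spike-in of array 2 was 1.35 times the median of the other 7 arrays, and that of array 1 was 0.715 times. The scanner software placed this spike-in out of its range on all 9 arrays, so weak labelling stays open for both. All 5 other tested members of the stromal, lymphoid, miR-17 cluster and inflammation lists also lay below their median of the other 7 arrays on both arrays. These values were scaled per array, so they cannot show a general loss of input. Array 1 of 0 Gy had the highest total signal (236074) and the most detected miRNAs (234) of the 9 arrays, and array 2 of 0 Gy the lowest total signal (28535). The hybridization spike-in was likewise highest on array 1 of 0 Gy (log10 signal 3.74) and lowest on array 2 of 0 Gy (2.52). On array 1 of 0 Gy miR-494-3p alone took 53.9% of the signal. The totals thus cannot be read as RNA input. Whether less cell RNA contributed stays open. Only if array 3 is a true 0 Gy sample, which stays open, does it speak against dose alone setting the order, and an effect of irradiation on part of it stays open too, with an exact p of 0.4.

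miR-3473b, miR-3963 and miR-6366 may differ with dose, as a hypothesis from these data. Leaving out the 2 irradiated arrays of high background gave a median difference of 2.60 (SE 0.59) at 1 against 0 Gy. The SEs given here are medians of the SEs of the 3 miRNAs. Array 1 of 1 Gy was the lowest 1 Gy array for each of them (10.64, 9.74 and 10.48), so leaving it out had to raise the difference. This says only that the difference did not come from high values on that array. Within the slide that holds 6 arrays the difference was 1.22 (SE 0.79), too imprecise to exclude the slide. Over 3 other scalings the lowest value was 0.74 (SE 1.52, scaled on all probes), too imprecise to exclude the scaling. Relative to the median of all tested miRNAs the difference was 1.82 on all probes, 2.69 after quantile normalization and 2.44 without scaling, against 2.47 as reported.

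In each pairwise comparison, 10 of 10 splits of the 6 arrays gave at least as many miRNAs as the real count of 0, which any split reaches, and so few splits allow no share under 0.05. The highest other count was 0 at 0.5 against 0 Gy, 0 at 1 against 0 Gy and 59 at 1 against 0.5 Gy. The split with 59 set arrays 1 and 3 of 1 Gy with array 1 of 0.5 Gy, so it joined the 2 arrays of high background and points to a structure of the samples. The 4 splits that part all 3 pairs, as the real one does, gave 0, and the 6 that part 1 pair gave up to 59. In the paired fit of 40 miRNAs the real count was 3, reached by 1 of 4 splits (highest other 1), and over the 134 it was 0, reached by 4 of 4 (highest other 1); so few splits allow no share under 0.05. For the lists, the real counts were 1, 1 and 0, the numbers of splits with as many were 5, 7 and 10 of 10, and the highest other counts were 6, 4 and 1. Of 100 drawn splits, 100 reached the real count of 0 in the F test (highest other 56) and 100 did so for the slope (highest other 21). Any split reaches a count of 0, so these numbers say nothing about chance.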
